A study of Mus musculus with 3 samples.

How the data were processed

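Gene expression was measured in mouse heart on 2-colour oligonucleotide microarrays with Agilent probe names. Total RNA came from 30 mg of heart, and the series describes 6 groups of 8 C57BL/6 animals. Per the labels, channel 1 and channel 2 of each sample held the hearts named first and second in its title, and both dyes are listed for both channels because dye swaps were merged. The deposited table gives 1 value per probe for each of 3 contrasts, and per the labels' descriptions each value merges 4 replicates with dye swaps. The single arrays, their intensities and the spread between replicates were not analysed here, so no p-value, standard error or replicate SD can be given for any gene. Nothing in the sources used here says whether the merged replicates came from separate animals or from pooled RNA. Scanner, background correction, normalization, filtering and the base of the logarithm are not given in the sources used here.

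The values deposited by the authors were read as log2 ratios. They held values on both sides of 0, with column medians as deposited of 0.0044 (esmolol over control), 0.0083 (LPS with esmolol over LPS) and 0.0072 (CLP over CLP with esmolol). The base is an assumption. The smallest deposited values were -3.12, -2.92 and -2.94, and the central 95% of probes in the LPS contrast spanned -0.59 to 0.60. Ranks, signs and list percentiles do not depend on the base, but every fold and every count at a fold threshold does. Scale and centring are stated by none of the sources used here, and the sources on direction differ for 1 contrast. The titles place the esmolol hearts first in the non-septic and LPS contrasts and second in the CLP contrast, while the series' design text speaks of treated hearts hybridized against untreated ones and makes no exception for CLP. The sign of the CLP contrast was turned, so that a value above 0 means higher with esmolol in all 3 contrasts, if the deposited values follow the order of the titles.

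Of 41174 probes, 35261, 34933 and 33501 had a value in the non-septic, LPS and CLP contrasts, and 14.4%, 15.2% and 18.6% were blank. Among the 953 probes for olfactory receptor genes the blank share was 27.9%, 27.8% and 33.2%. A single exact value recurred in each column, at 359, 526 and 538 probes, while the next most frequent value recurred at 25, 15 and 26. Of these probes, 282 were shared by all 3 columns. They included many probes for abundant heart transcripts, such as 10 of 20 measured sarcomere genes in the LPS and in the CLP contrast, and were read as saturated in both channels, which gives no ratio. They were kept, and the counts, correlations, fixed lists and named genes were repeated without them. Gene lists written later were not.

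Genes were named from the platform annotation and from RefSeq gene symbols of assembly GRCm38.p6, used for names alone. Of the probes, 32664 carried 1 gene, 45 carried several and were left out, and 8465 were unnamed here. The gene ID of 32524 of the single-gene probes matched the RefSeq table. This gave 19532 genes, of which 17814, 17733 and 17339 were measured in the 3 contrasts and 16975 in all of them. Probes of a gene were collapsed by their median. The pooled SD between probes of the same gene was 0.11 (non-septic), 0.24 (LPS) and 0.10 (CLP) on the log2 scale, over 7472, 7394 and 7105 genes with more than 1 probe. This is the only measure of error within the table, and it covers neither animals nor hybridizations.

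Genes were counted as higher or lower from 1.5-fold on, which is 0.585 on the log2 scale. Gene lists, 35 in all, were fixed before the data were examined, together with the rule for named genes and the alternatives. The median log2 ratio of each list was set against 10000 random lists of the same size, drawn from the named genes measured in that contrast and matched on having 1 or more than 1 probe. Matching on expression level was not possible without intensities. A list outside the central 95% of its random lists is called apart from them. About 1.75 of 35 lists would be so by chance in each contrast if list members varied independently. This describes the merged hybridizations and is no test between conditions. On values reshuffled over genes, 5.0%, 4.0% and 4.0% of 200 unchanged lists of 20 genes were called apart in the non-septic, LPS and CLP contrasts. Of 200 lists shifted by 0.1, 96.0%, 34.5% and 98.5% were called, and of lists shifted by 0.2, 100%, 88.0% and 100%, so the LPS contrast had the least power for small shifts. Reshuffling removes any correlation between members of a list. The share of unchanged lists called, and the 1.75, can therefore be too low for lists of co-regulated genes. Contrasts were compared by Pearson and Spearman correlation across genes and by the overlap of genes past 1.5-fold, beside the overlap expected of independent lists.

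Named genes are, per contrast, the 10 highest and 10 lowest among genes with a single symbol, without predicted or clone names and with all probes on the same side of 0. The highest and lowest member of each fixed list, a fixed set (Il6, Tnf, Il1b, Nos2, Nppa, Nppb, Myh6 and Myh7) and the 5 largest shared changes per direction in LPS and CLP hearts were added. Other list members are named as examples of a count and were chosen after their values were seen. Further members of the fixed set and of some lists were not analysed here. Alternatives were the mean of probes, centring on the median gene, genes with agreeing probes, genes measured in all contrasts, genes with 1 probe, counts of probes, a 2-fold threshold, the unturned CLP sign, capped extremes, unmatched random lists and lists without their farthest member. Added after seeing the data were leaving out the recurring value, leaving out marker genes of other tissues, and reading the values as natural or base-10 logarithms. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.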

Results

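The hearts of C57BL/6 mice were profiled with and without esmolol, a short-acting blocker of the beta-1 adrenergic receptor, given as a continuous infusion of 20 mg/kg/h. There were 3 contrasts: esmolol against untreated animals without sepsis, esmolol in mice given lipopolysaccharide (LPS, a bacterial cell wall component that provokes systemic inflammation), and esmolol in mice with cecal ligature and perforation (CLP, a model of abdominal sepsis). The question was how the drug alters myocardial gene expression in each setting. Each contrast is a single merged log ratio per probe from 4 replicates, so the values below carry no replicate error and no difference was tested. "Higher" and "lower" describe the sign and size of that merged ratio, read as log2. Their direction rests on the order of the sample titles and channels, since the labels give both dyes for both channels. In the non-septic and LPS contrasts this order and the series' design text both put treated hearts first, which makes the direction likely. In the CLP contrast the title puts untreated hearts first and the design text treated ones, so its direction is not settled. At 1.5-fold, 39 genes were higher and 43 lower with esmolol in non-septic hearts, 365 higher and 401 lower in LPS hearts, and 142 higher and 23 lower in CLP hearts. These were 0.460%, 4.32% and 0.952% of the genes measured. The spread of all genes was also wider in the LPS contrast (SD 0.28 on the log2 scale) than in the non-septic (0.14) and CLP (0.16) contrasts, as was the SD between probes of a gene (0.24 against 0.11 and 0.10).

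In non-septic hearts, the cytokine and interferon lists had medians below random lists with esmolol, and the clock and glucocorticoid-responsive lists had medians above them. The lowest gene was Saa3, an acute phase serum amyloid (log2 ratio -3.12, 8.71-fold lower; probe A_51_P337308). The chemokines Cxcl5 (-2.88), Cxcl10 (-2.78), Cxcl1 (-1.80) and Cxcl9 (-1.60), the immune checkpoint ligand Cd274 (-2.46) and the iron-binding acute phase protein Lcn2 (-1.68) followed. Nppb, which encodes B-type natriuretic peptide, was lower at 2 probes (-1.43 ± 0.23, SD between probes, n = 2 probes). Ccdc172 (-1.33) and the interferon-inducible GTPase Igtp (-1.25) completed the 10 lowest. The highest genes were Ahsg, a liver-type plasma glycoprotein (1.03), the alcohol dehydrogenase Adh1 (0.93 ± 0.10, n = 2 probes), the clock-controlled gene Ciart (0.83), Klhl38 (0.81) and Sln, the sarcoplasmic reticulum regulator sarcolipin of the atria (0.80). Slc1a3 (0.74), Tnfaip8l3 (0.74) and Fkbp5, a glucocorticoid receptor co-chaperone (0.73 ± 0.04, n = 3 probes), were next. The olfactory receptors Olfr33 (0.90) and Olfr215 (0.83), with 1 probe each, ranked 3 and 5 among the 10 highest. Only Ahsg and Adh1 ranked above Olfr33, so ratios of the size of the other genes named here also occurred at olfactory receptor probes.

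Of 35 fixed lists, 7 lay above and 6 below their random lists in non-septic hearts. Pro-inflammatory cytokines and chemokines had a median of -0.23 (central 95% of random lists -0.06 to 0.06), with 6 of 20 measured members lower by 1.5-fold or more and none higher. Interferon-stimulated genes had a median of -0.18, with 6 of 25 lower, among them Ifit1 (-0.77), Irgm1 (-0.70) and Ifit2 (-0.66). Stress and fetal program genes (median -0.17, 10 of 12 below 0), heat shock and unfolded protein response genes (median -0.12) and immediate early genes (median -0.11) were also below random lists. The heat shock list ranged from Hsp90aa1, a cytosolic chaperone (-0.66), to Herpud1 (0.63), and Atf3, a stress-induced transcription factor, was the lowest immediate early gene (-0.56). Circadian clock genes had a median of 0.20, with 4 of 17 genes past 1.5-fold, Ciart, Dbp (0.69), Per1 (0.60) and Per3 (0.60), and 6 below 0, of which Arntl, which encodes the core activator BMAL1, was lowest (-0.29). Glucocorticoid-responsive genes had a median of 0.26, with 13 of 14 above 0 and 2 past 1.5-fold, Fkbp5 and Per1. Per1 belongs to both lists, so these are not fully separate results. Other inflammatory lists lay within the random range, with medians of -0.02 for NF-kB and Toll-like receptor genes, -0.02 for acute phase proteins, 0.03 for complement and -0.04 for adhesion and coagulation. Of the 14 measured acute phase genes, 3 were nevertheless lower by 1.5-fold or more, Saa3 and Lcn2 among them, and 0 were higher by as much. Smaller shifts above random lists were seen for the atrophy, ubiquitin and autophagy list (median 0.07, highest Fbxo32 at 0.44), apoptosis genes (0.06, highest Bcl2l1 at 0.43), monocyte and macrophage markers (0.08, highest Cd163 at 0.48) and fibroblast and extracellular matrix genes (0.05, highest Lox at 0.59). Atrial markers were above random lists in the same contrast (median 0.41), and blood markers below (median -0.11, lowest Pf4 at -0.25). Without their farthest members the medians of the fibroblast (0.04) and macrophage (0.06) lists lay within the random range. With genes of 1 probe alone, so did those of the apoptosis (0.01), atrophy (0.02) and blood (-0.06) lists.

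**Figure D1:**
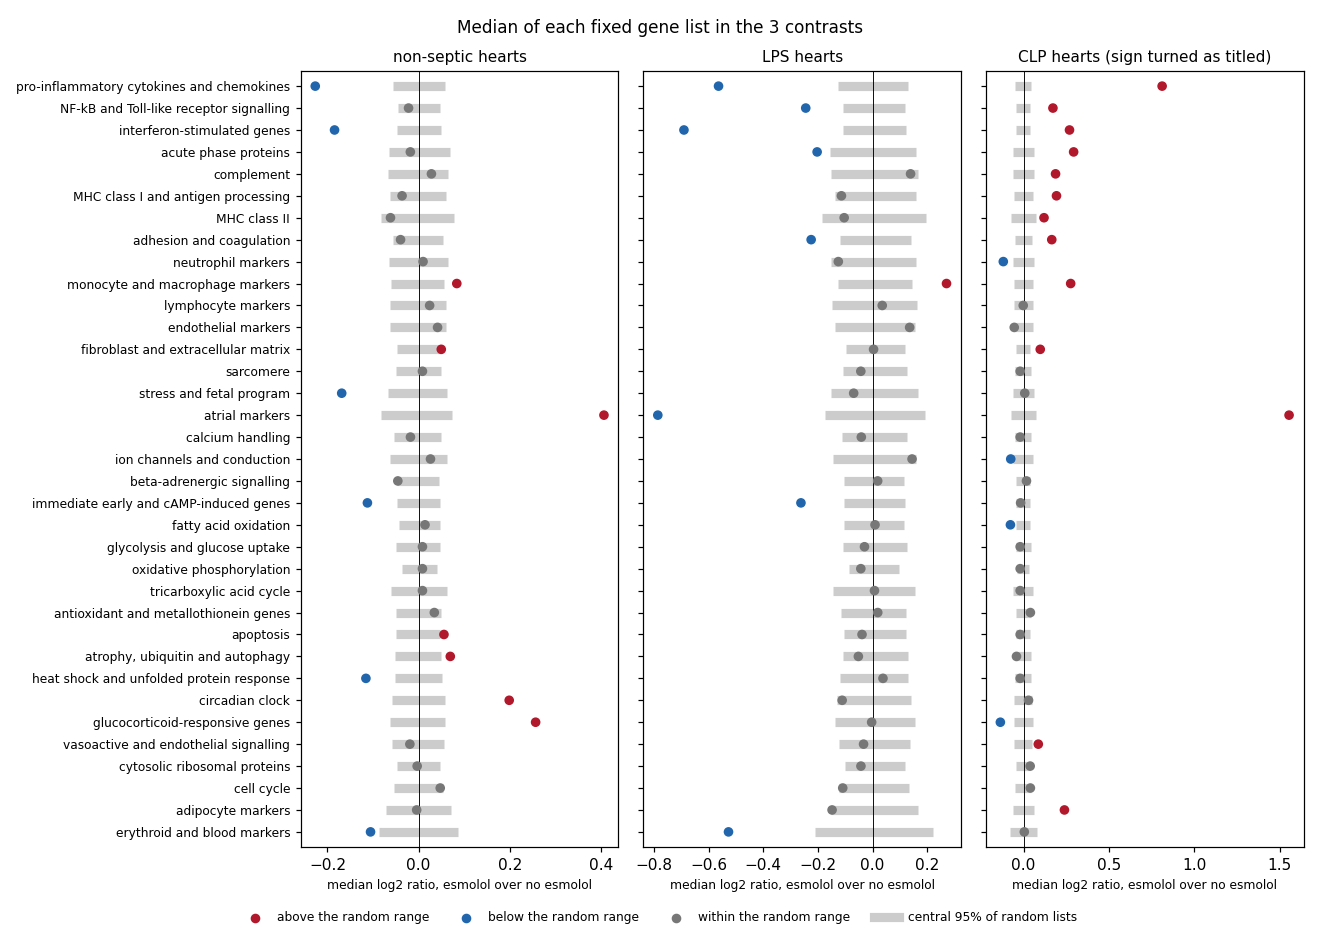
Median log2 ratio (horizontal axis, esmolol over no esmolol) of each of the 35 fixed gene lists (vertical axis) in non-septic, LPS and CLP hearts; the horizontal scales differ between panels. Grey bars are the central 95% of 10000 random lists of the same size, and red and blue points are list medians above and below that range, 7 and 6 in non-septic, 1 and 8 in LPS and 13 and 4 in CLP hearts.

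In LPS hearts, 16 of 25 interferon-stimulated genes and 9 of 22 cytokines and chemokines were lower with esmolol by 1.5-fold or more, and none of either list was higher by as much. Cxcl10 (-2.56, 5.88-fold lower; probe A_51_P432641) and Cxcl9 (-2.13), both interferon-induced chemokines, were the lowest genes. Calhm6 (-1.99), Ifit2 (-1.92 ± 0.03, n = 2 probes), the guanylate-binding protein Gbp2 (-1.70) and Cd274 (-1.65) were among the 10 lowest, together with the platelet chemokine Ppbp (-1.81), the immunoglobulin segment Ighv1-19 (-1.79), the fast skeletal myosin light chain Mylpf (-1.72) and Olfr691 (-1.79). The highest were the nuclear RNA Neat1 (1.58), Cd300lg (1.53 ± 0.59, n = 2 probes), the glycerol channel Aqp7 (1.52 ± 1.08, n = 2 probes), the endothelial transcription factor Sox18 (1.44), Adgrl4 (1.42), Hsd11b1, which regenerates active glucocorticoid (1.39), Btnl9 (1.36 ± 1.59, n = 2 probes), Klhl38 (1.25), Zxda (1.25) and Slc26a10 (1.23). The probes of Btnl9 and Aqp7 had the same sign but different sizes. The olfactory receptor Olfr691, with 1 probe, ranked 6 among the 10 lowest. Its ratio was larger in size than those of Gbp2, Cd274 and every gene named here as highest, so ratios of that size also occurred at an olfactory receptor probe.

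Interferon-stimulated genes showed the broadest shift among the immune lists in LPS hearts, with a median of -0.69 (random lists -0.11 to 0.12) and 16 of 25 measured members lower by 1.5-fold or more. Gbp5 (-1.59), Gbp3 (-1.38), Ifit1 (-1.12), Rsad2 (-1.06) and Isg15 (-0.93) were examples, and Oas1a (0.05) was the sole member above 0. Among cytokines and chemokines the median was -0.56 and 9 of 22 were lower, with Il6 at -1.55, Csf3, the granulocyte growth factor, at -1.44, the prostaglandin synthase Ptgs2 at -1.24 and the inducible nitric oxide synthase Nos2 at -0.85. Tnf (0.16) and Il1b (0.12) were the 2 members above 0. NF-kB and Toll-like receptor genes had a median of -0.24, with the inhibitory feedback gene Tnfaip3 (-1.41) lowest. Adhesion and coagulation genes had a median of -0.22, with the endothelial selectins Sele (-0.88) and Selp (-0.85) and Icam1 (-0.82) lower and Icam2 (0.87) higher. Acute phase proteins (median -0.20, lowest Hp at -0.93, highest Itih4 at 0.66) and immediate early genes (median -0.26, lowest Atf3 at -1.29) were also below random lists. Limited to genes measured in all 3 contrasts, the acute phase median (-0.17) lay within the random range. Monocyte and macrophage markers were the 1 list above random lists (median 0.27, 4 of 15 higher), with Cd163 at 0.89 and the mannose receptor Mrc1 at 0.81. Of its members 5 lay below 0, among them Lgals3 (-0.34), Mpeg1 (-0.27) and Fcgr3 (-0.19). In the same contrast atrial markers (median -0.79, 5 of 9 lower) and blood markers (median -0.53, 3 of 8 lower) were below random lists. Circadian clock genes had a median of -0.11, within the random range, but with Dbp (0.83) highest and Arntl (-0.96) lowest, as members of opposite sign in 1 list. Their median lay below that range without the farthest member and with genes whose probes had the same sign (-0.18 in each).

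**Figure D2:**
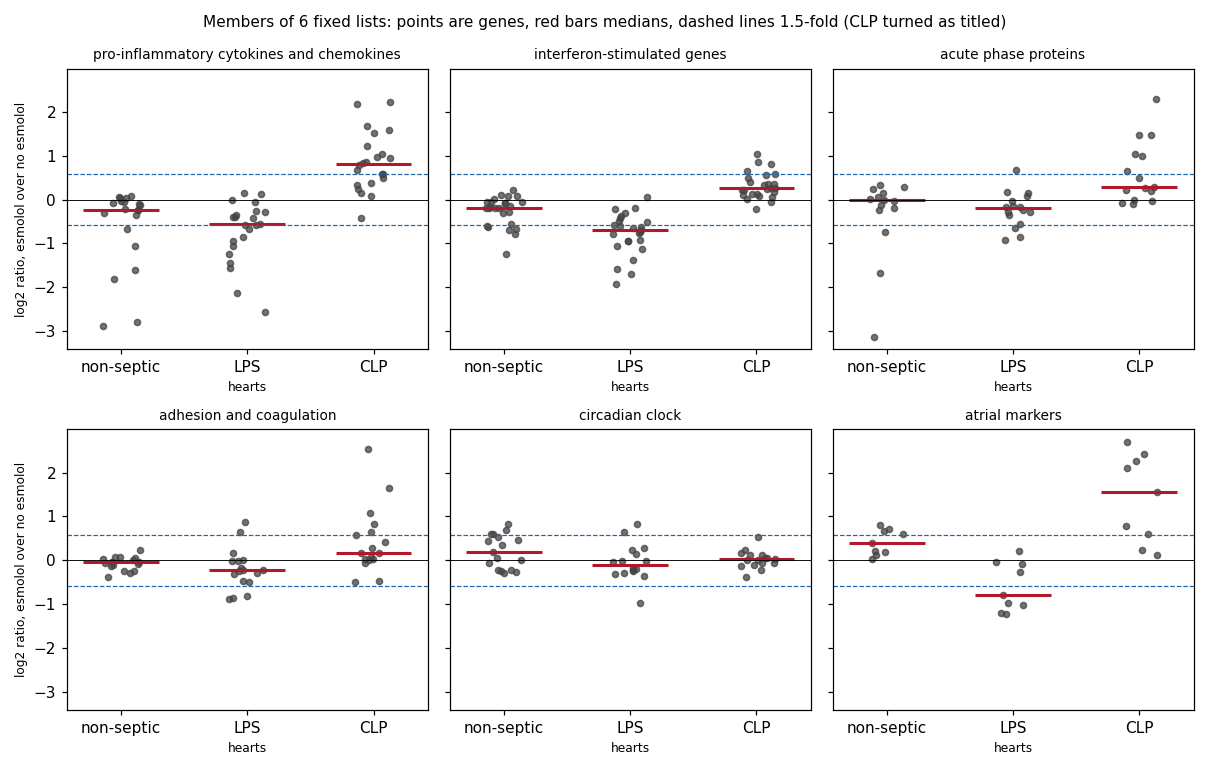
Log2 ratio (vertical axis, esmolol over no esmolol) of each measured member of 6 fixed lists in non-septic, LPS and CLP hearts (horizontal axis). Points are genes, red bars the list medians and dashed lines 1.5-fold; the cytokine medians are -0.23, -0.56 and 0.81, and the atrial medians 0.41, -0.79 and 1.55.

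In CLP hearts the title names the untreated hearts first, and with the sign turned accordingly the cytokine, acute phase and adhesion lists had medians above random lists with esmolol. If the deposited values do not follow the title, every direction in this contrast reverses. The highest gene was Hamp, which encodes the iron hormone hepcidin (2.94, 7.66-fold higher; probe A_52_P669922). Sele (2.54), the B-cell chemokine Cxcl13 (2.45), haptoglobin (Hp, 2.29), Csf3 (2.22) and Cxcl5 (2.18) were among the 10 highest, as were the atrial genes Bmp10 (2.69), Sln (2.42) and Myl7 (2.25) and the brown fat uncoupling protein Ucp1 (2.40). The lowest were Sox18 (-1.47), the retinol-binding protein Rbp7 (-0.90 ± 0.50, n = 2 probes), the actin-binding signalling protein Abra (-0.87), the neutrophil gene Retnlg (-0.85), Trmt5 (-0.85), Depp1 (-0.77), Tcim (-0.72 ± 0.004, n = 2 probes), Shld1 (-0.70), the chemokine receptor Cxcr3 (-0.70) and Ccn2, a matricellular growth factor (-0.67).

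Of the 35 lists, 13 lay above and 4 below random lists in CLP hearts. Cytokines and chemokines had a median of 0.81 (random lists -0.05 to 0.05), with 15 of 22 measured members higher by 1.5-fold or more, including Cxcl9 (1.67), Cxcl10 (1.59), Ptgs2 (1.52), Il6 (1.22) and Il1b (0.84); Tnf was at 0.49, Nos2 at 0.15 and Il10, an anti-inflammatory cytokine, was lowest (-0.41). Acute phase proteins had a median of 0.29 with 6 of 15 higher, among them Saa3 (1.48), Saa2 (1.47), Orm1 (1.04) and Saa1 (1.00). Interferon-stimulated genes had a median of 0.27, with 5 of 25 higher and Gbp2 (1.03) highest. Adhesion and coagulation genes (median 0.17, 5 of 17 higher, with Selp at 1.64 and Vcam1 at 1.07), NF-kB and Toll-like receptor genes (0.17, highest Tnfaip3 at 0.80), MHC class I (0.19, highest Tap1 at 0.53), MHC class II (0.12, highest H2-Aa at 0.50), complement (0.19, highest Cfb at 1.01), vasoactive signalling (0.09, highest Hif1a at 0.44) and fibroblast and matrix genes (0.10, highest Col3a1 at 0.71) were above random lists. Monocyte and macrophage markers had a median of 0.28, with Adgre1 (0.92), the gene of the F4/80 antigen, highest. Below random lists were neutrophil markers (median -0.12, lowest Retnlg), glucocorticoid-responsive genes (-0.14, lowest Errfi1 at -0.28), fatty acid oxidation genes (-0.08, 26 of 29 below 0, 5 of them on the recurring value, lowest Acot1 at -0.52) and ion channels (-0.07, lowest Kcnj2 at -0.46). Atrial markers (median 1.55, 7 of 9 higher) and adipocyte markers (median 0.24, 4 of 12 higher) were above random lists in the same contrast. Without their farthest members the adipocyte (0.04) and ion channel (-0.05) medians lay within the random range.

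The contrasts were compared across the genes measured in both. Genes are not independent replicates, so the coefficients describe these merged values. LPS and CLP hearts correlated negatively in the titled direction (Pearson r = -0.18, Spearman rho = -0.08, 17089 genes), and the same values correlate positively, with Pearson r = 0.18, if the CLP sign is not turned. Of the genes past 1.5-fold in both, 47 went in opposite directions, where independent lists would share 3.63, and 8 in the same direction, where 3.43 would be shared. Of the 47, 42 were lower in LPS and higher in CLP hearts, led by Cxcl9, Cxcl10, Csf3, Ptgs2 and the atrial Myl7 (-1.23 and 2.25). The other 5 were higher in LPS and lower in CLP hearts, among them Rbp7 (1.05 and -0.90), whose 2 probes in LPS hearts lay on both sides of 0. With all probes on the same side, the largest such values were those of Sox18 (1.44 and -1.47), Adgrl4 (1.42 and -0.66), Retnlg (0.65 and -0.85), Slc9a3r2 (0.89 and -0.62) and Btnl9 (1.36 and -0.54, under 1.5-fold in CLP). Col3a1 (0.81 and 0.71), the chemokine Ccl12 (0.65 and 1.26), Lyz1 (0.63 and 0.67), Prg4 (1.09 and 0.62) and Lyz2 (0.62 and 0.74) were higher in both, the lysozymes being myeloid genes. Abra (-0.86 and -0.87), the anti-proliferative gene Btg2 (-0.68 and -0.59), the prolyl hydroxylase Egln3 (-0.66 and -0.52), Otud1 (-1.25 and -0.50) and Resf1 (-0.46 and -0.59) had the largest values below 0 in both. Of these, Abra and Btg2 were past 1.5-fold in both contrasts, Egln3 and Otud1 in LPS hearts alone and Resf1 in CLP hearts alone. Of the lists, 6 lay apart from random lists on opposite sides in LPS and CLP hearts, and 1, the macrophage markers, on the same side. With the CLP sign unturned, 1 would lie on opposite sides and 6 on the same side.

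Non-septic and LPS hearts correlated positively (Pearson r = 0.15, Spearman rho = 0.12, 17334 genes). They shared 24 genes past 1.5-fold in the same direction, 16 of them lower, where independent lists would share 1.42, and 6 in opposite directions, where 1.42 would also be shared. Cxcl10, Cxcl9, Cd274 and Ifit2 were lower and Klhl38 higher in both. Non-septic and CLP hearts correlated negatively in the titled direction (Pearson r = -0.15, Spearman rho = -0.10, 17166 genes), with 15 genes past 1.5-fold in opposite directions against 0.301 by chance and 5 in the same direction against 0.274. No difference between contrasts was tested.

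**Figure D3:**
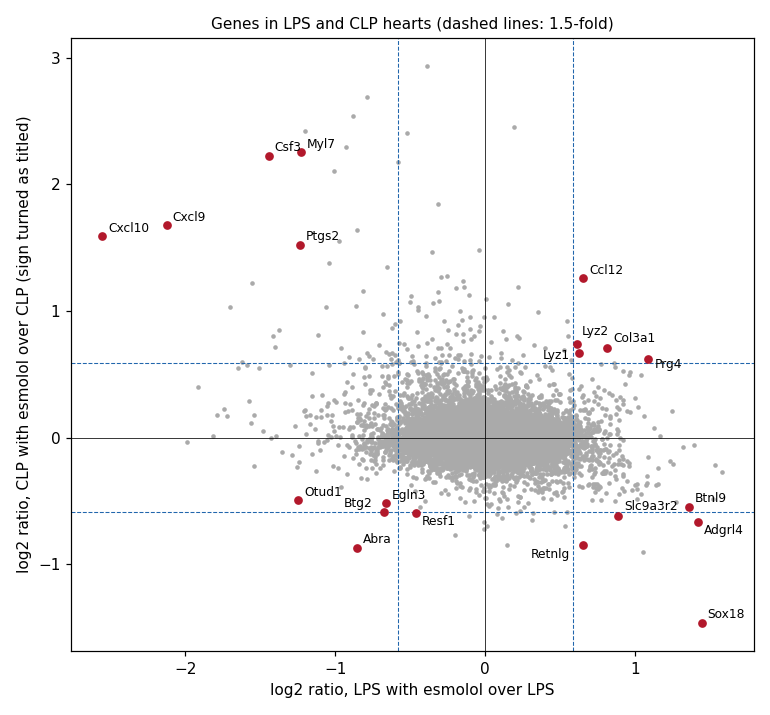
Log2 ratio of each gene in LPS hearts (horizontal axis) and CLP hearts (vertical axis, sign turned as titled), with dashed lines at 1.5-fold. Red points are the 5 largest shared values in each combination of directions among genes with all probes on the same side of 0; Cxcl9, Cxcl10, Csf3, Ptgs2 and Myl7 lie at the upper left and Sox18 at the lower right.

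Contractile and energy genes showed few large ratios. No sarcomere, calcium handling, fatty acid oxidation or tricarboxylic acid cycle gene reached 1.5-fold in any contrast, except Tnnt2, cardiac troponin T, in LPS hearts (0.62 ± 0.94, n = 2 probes, 1 of them on the recurring value described next). Of the oxidative phosphorylation genes 1, the ATP synthase subunit gene Atp5c1, was past 1.5-fold, in LPS hearts (-0.84). Myh6, the main adult cardiac myosin, was at 0.01, -0.04 and -0.02 in non-septic, LPS and CLP hearts, and Myh7, the fetal isoform, at 0.03, 0.58 and -0.23. Nppa, atrial natriuretic peptide, was at 0.41, -0.09 and 0.78, and Nppb at -1.43, -0.04 and 0.60. These lists hold many transcripts on the recurring, apparently saturated value. It covered 10 of 20 sarcomere genes in LPS and in CLP hearts, 21 and 22 of 40 oxidative phosphorylation genes, both probes of Nppb and 1 of 2 of Nppa in LPS hearts, and both probes of Myh6 in LPS and CLP hearts and 1 of 2 in non-septic hearts, so their ratios near 0 are not evidence of equal expression. Without these probes the sarcomere list lay above random lists in LPS hearts (median 0.21) and below them in CLP hearts (median -0.12), and fatty acid oxidation genes stayed below them in CLP hearts (median -0.11). Glycolysis genes lay within the random range in every contrast (medians 0.01, -0.03 and -0.02; lowest Hk2 at -0.64 in LPS hearts), as did tricarboxylic acid cycle and calcium handling genes. Genes of beta-adrenergic signalling, the pathway esmolol blocks, had medians of -0.05, 0.02 and 0.02, all within the random range. The non-septic median lay below it with the mean of probes (-0.06) and without the farthest member (-0.05). The cyclic nucleotide phosphodiesterase Pde2a (0.92) and the adenylyl cyclase Adcy6 (0.60) were higher in LPS hearts. Antioxidant genes also lay within it (medians 0.03, 0.02 and 0.04), with catalase (Cat, 0.68) highest in LPS hearts and the heme oxygenase Hmox1 (0.99) highest in CLP hearts. In CLP hearts the antioxidant median lay above it without the recurring value (0.07) and with genes of 1 probe (0.09).

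The general endothelial list stayed within the random range (medians 0.04, 0.14 and -0.05), as did lymphocyte markers (0.02, 0.04 and -0.002), ribosomal proteins (-0.003, -0.04 and 0.04) and cell cycle genes (0.05, -0.11 and 0.04). Ribosomal proteins lay above it in CLP hearts without the recurring value (0.06) and, at an equal median, without genes of other tissues. Cell cycle genes lay above it in CLP hearts with the mean of probes (0.05) and in non-septic hearts with genes whose probes had the same sign (0.07). Neutrophil markers were within it in non-septic and LPS hearts (0.01 and -0.13), but above it in non-septic hearts with genes of 1 probe (0.10). Atrial markers lay apart from random lists in all 3 contrasts, and blood markers in 2 (medians -0.11 and -0.53 in non-septic and LPS hearts, against 0.005 in CLP hearts), beside each of the immune shifts given above. MHC class I genes were within it in LPS hearts (median -0.11), but below it without the recurring value (-0.37). With atrial, adipocyte, blood and skeletal muscle genes left out, a choice made after seeing the data, 39 genes were past 1.5-fold in opposite directions in LPS and CLP hearts, and 130 were higher and 23 lower in CLP hearts. Leaving out these genes keeps the ratio of every other gene as it was. It therefore cannot show whether RNA of other tissues moved the remaining genes.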

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

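The tests of the CLP title order and of neutrophils were chosen only after their results were seen. The test genes for atrial tissue were listed after the atrial pattern was seen but before their own values were looked at.

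Genes and lists on opposite sides in LPS and CLP hearts are given here as the LPS minus the CLP log2 ratio, with the CLP sign as titled. Each side is 1 merged value, and the difference was not tested. With the CLP sign unturned, none of these 25 results lies on opposite sides and all 25 differences are smaller, which follows from choosing results of opposite sign. The difference would then be -0.97 for Cxcl10, -0.45 for Cxcl9, 0.78 for Csf3, 1.66 for Sele, 1.36 for Hp, -0.02 for Sox18, 0.25 for the cytokine list and 0.77 for the atrial list. As titled, among inflammatory genes the difference was -4.14 for Cxcl10, -3.80 for Cxcl9, -3.67 for Csf3, -3.42 for Sele, -3.22 for Hp, -2.78 for Il6, -2.76 for Ptgs2, -2.73 for Gbp2, -2.22 for Tnfaip3 and -1.26 for Igtp. Among list medians it was -1.38 for cytokines and chemokines, -0.96 for interferon-stimulated genes, -0.50 for acute phase proteins, -0.42 for NF-kB and Toll-like receptor genes and -0.39 for adhesion and coagulation. Atrial markers differed by -2.34 as a list, with Sln at -3.62, Bmp10 at -3.48 and Myl7 at -3.48, and the adipocyte gene Car3 differed by -1.44. Positive differences were seen for Sox18 (2.91), Adgrl4 (2.08), Rbp7 (1.95), Slc9a3r2 (1.51) and Retnlg (1.5).

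For the inflammatory genes of CLP hearts, more neutrophils in the hearts with the higher cytokine values would put the neutrophil markers on the cytokine side. Their median was -0.12, below random lists, while the cytokine median was 0.81. Of 13 measured markers 11 lay below 0, 2 of them by 1.5-fold or more, and Fpr2 (0.60) was highest. The opposite sides hold for either sign of the contrast, since turning it turns both. Because this test was chosen after its result was seen, it is no independent evidence against neutrophils. In LPS hearts the neutrophil median (-0.13) lay on the same side as the cytokine median (-0.56) and within the range of random lists. Neutrophils stay open there too. Monocyte and macrophage markers lay on the cytokine side in CLP hearts for either sign (median 0.28 as titled, 13 of 14 above 0). In LPS hearts they lay on the other side (median 0.27). A different macrophage content of the hearts was not tested. A CLP column deposited against the order of its title cannot be told apart from a truly opposite response: the correlation across genes with the LPS contrast was -0.18 in the titled order, which both would give, and the series' design text names treated hearts first where the title names untreated ones. A different response to esmolol in the 2 sepsis models stays open and was not tested.

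For the atrial genes, a different share of atrial tissue in the 30 mg samples is a candidate explanation in CLP hearts. There, 6 measured atrial-enriched genes outside the fixed list had a median of 0.16, above random lists, while the median of the fixed list was 1.55. Of the 6, 4 lay above 0, Kcnj3 (-0.03) and Gja5 (-0.07) below it, and none reached 1.5-fold. A set of 5 ventricle-enriched genes had a median of -0.15, below random lists, though 2 of these 5, Myl3 and Irx4, lay on the recurring value. Of the listed genes, 2 atrial-enriched and 3 ventricle-enriched ones also belong to fixed lists of other kinds. In LPS hearts (0.03) and non-septic hearts (0.06) the median of the atrial-enriched genes lay within the range of random lists. So did that of the ventricle-enriched genes (-0.11 and 0.04). In LPS hearts 0 of these 5 lay above 0, the side of the atrial markers (-0.79) rather than the opposite one, though Myl2 and Myl3 had probes on the recurring value. Atrial tissue share and a response of the atrial genes cannot be told apart in any of the 3 contrasts, since a response could also place the atrial-enriched genes of CLP hearts above random lists. An effect of esmolol on atrial genes stays open in all 3 contrasts.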

How the results depend on the processing

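The recurring value, the marker genes of other tissues and both other log bases were chosen as alternatives only after the data were seen. No paired analysis was possible because replicates were merged and no result comes from a test. Of the named genes' values under the alternatives, 1926 stayed within the probe spread, 5 moved further and none reversed. Of list medians, 850 stayed, 104 moved and 17 reversed, all 17 with the CLP sign unturned. That sign also turns each named gene's CLP value by construction. Many of the values that stayed could not move. Mean and median are equal for a gene with a single probe. Settings that only leave out genes keep the value of every other named gene. Unmatched random lists leave every list median as it was. The counts of values that stayed are therefore no measure of robustness. Precision is limited by the single merged value per probe, and signal over background was not analysed here.

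With the CLP sign not turned, 23 genes were higher and 142 lower in CLP hearts, and 4 lists lay above and 13 below random lists. Correlations were 0.1787 (Pearson) and 0.079 (Spearman) with LPS and 0.1478 and 0.1007 with non-septic hearts. Genes past 1.5-fold in the same and in opposite directions were 47 and 8 with LPS and 15 and 5 with non-septic hearts. List medians became -0.8113 (cytokines), -0.1722 (NF-kB), -0.2692 (interferon), -0.2934 (acute phase), -0.1875 (complement), -0.193 (MHC class I), -0.12 (MHC class II), -0.1654 (adhesion), 0.1183 (neutrophil), -0.2761 (macrophage), -0.098 (fibroblast), -1.5543 (atrial), 0.0748 (ion channels), 0.0766 (fatty acid oxidation), 0.1355 (glucocorticoid), -0.0866 (vasoactive) and -0.2396 (adipocyte).

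Counts of higher and lower genes followed the scale by construction. Read as natural logarithms, they were 128 and 154 (non-septic), 1171 and 1135 (LPS) and 303 and 94 (CLP), and as base-10 logarithms 1057 and 1293, 4259 and 4026, and 1329 and 974. At 2-fold they were 1 and 16, 32 and 75, and 43 and 1, with same and opposite overlaps of 0 and 12 (LPS and CLP), 6 and 0 (non-septic and LPS) and 0 and 5 (non-septic and CLP). Counted as probes they were 80 and 100, 938 and 900, and 227 and 53.

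The cause was not tested for the remaining shifts. Lists above random lists in LPS hearts numbered 2 with the mean of probes and 2 without the recurring value. Genes with all probes on the same side gave correlations of 0.1685 (Pearson) and 0.1313 (Spearman) for non-septic and LPS hearts. Genes with 1 probe gave -0.1535 (Pearson) and -0.0277 (Spearman) for LPS and CLP, with 5 genes shared in the same direction, and -0.0739 (Spearman) for non-septic and CLP. With capped extremes the Pearson correlations were -0.1503 (LPS and CLP), 0.1278 (non-septic and LPS) and -0.1152 (non-septic and CLP). Without atrial, adipocyte, blood and skeletal muscle genes, 2 genes were opposite in non-septic and LPS hearts and 1 was shared in the same direction in non-septic and CLP hearts.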

Other observations

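The lists used in the tests of skeletal muscle and capillary genes were written only after the extremes of each contrast were seen, and before the values of the genes tested were looked at.

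Arntl, which encodes the clock activator BMAL1, was the lowest circadian gene in non-septic (-0.29) and LPS hearts (-0.96). In CLP hearts it was the lowest with the sign as titled (-0.39) and would be the highest with the sign unturned. The muscle ubiquitin ligase Fbxo32 was the highest gene of the atrophy list in non-septic (0.44) and LPS hearts (0.73). Egln3, which marks proteins of the oxygen response for degradation, was lower with esmolol in non-septic (-1.01) and LPS hearts (-0.66). In CLP hearts it was lower with the sign as titled (-0.52) and would be higher with the sign unturned. The gap junction gene Gja1 was the lowest ion channel and conduction gene in non-septic hearts (-0.50) and the highest in LPS hearts (0.96).

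Single probes of Mylpf (-1.72), Atp2a1 (-2.92), Myh4 (-1.98) and Tnnt3 (-1.45), all fast skeletal muscle genes, were among the lowest in LPS hearts, while over both probes Tnnt3 was at -0.55, under 1.5-fold. Skeletal muscle RNA in the untreated LPS hearts is a candidate explanation: 12 further fast muscle genes had a median of -0.27, below random lists, with Tnni2 at -1.43, Actn3 at -1.12 and Myh1 at -0.87. Against a uniform share, Tnnc2 (-0.18), Pvalb (-0.25) and Myh2 (-0.11) lay closer to 0, and Apobec2 (0.23) and Mybpc2 (0.18) were higher. The other probe of Atp2a1 and of Myh4 lay on the recurring value, and that of Tnnt3 was at 0.35. How many of these genes heart muscle itself expresses could not be read from ratios, and a response of heart muscle to esmolol was not tested.

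A hypothesis is that capillary endothelial genes shift as a group, higher in LPS and lower in CLP hearts with esmolol as titled. It arose from Sox18, Btnl9, Rbp7, Aqp7, Cd300lg and Adgrl4. Among 13 other genes known from capillary endothelium the median was 0.30 in LPS hearts, above random lists, and -0.18 in CLP hearts, below them, a difference of 0.48. With the CLP sign unturned the CLP median would be 0.18, above 0 as in LPS hearts, and the difference 0.13, so the opposite shift holds for the titled sign alone. In LPS hearts 10 of the 13 genes lay above 0, counting Sox17 (0.01), which has a probe on the recurring value. Gpihbp1, which carries lipoprotein lipase across capillaries (0.87 and -0.26), Ptprb (0.85 and -0.22) and Myct1 (0.74 and -0.40) were examples, while Sox7 (-0.48 in LPS hearts), Meox2 (-0.09 in LPS hearts) and Rasip1 (-0.30 and 0.24) went against it. The general endothelial list lay within the range of random lists in both contrasts, and the difference between contrasts was not tested. Atrial markers lay on the side opposite to these capillary genes in both contrasts as titled (medians -0.79 in LPS and 1.55 in CLP hearts). A different share of tissues in the samples could therefore not be told apart from a response of capillary genes.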
